A study of Homo sapiens with 8 samples.

How the data were processed

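Biotinylated cRNA from 8 RNA samples of HaCaT cells was hybridised to Illumina bead arrays, 2 arrays for each of 4 groups: control, FA, rapamycin and FA+rapamycin. RNA was taken with a column kit and its amount and quality were read on a spectrophotometer, per the labels' protocols. The labels describe the experiments as performed in duplicate and number the arrays 1 and 2 in each group; they do not say whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The deposited scanner table gives for each probe and array an intensity on a linear scale, not background corrected or normalized as far as its values show, and a detection p-value, per the file headers; it holds 48203 rows, of which 770 are negative controls and 117 other controls. The deposited value table holds log2 values for 47316 probes, made with limma per the submitters' processing notes, which give no version. The scanner's version, the background correction and the annotation the authors used are not given in the sources used here. The scanner table carries another kind of probe number than the value table, so rows were joined by the rank of their values on each array: all 47316 probes fell in the same order on all 8 arrays. Normalization of the scanner intensities as below came within 0.0286 of the deposited log2 values (median difference 0.00214, lowest correlation over the 8 arrays 0.999989), which settles their scale as log2 with no centring by gene.

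The intensities were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3: normexp fitted on the negative control probes, an offset of 16, quantile normalization between arrays and log2. Probes with a detection p under 0.05 on at least 2 of the 8 arrays were kept, 22752 in all. Gene symbols came from the platform annotation, in which 30110 probes had 1 symbol, 8 had several and 17198 had none; probes with several or none were left out of the gene tests. The gene numbers of 30071 of these probes were found in the RefSeq table of GRCh38.p14, which was used for names only, and no coordinate is given because the sources name no genome build. For each of the 12398 genes left, the probe with the highest mean signal over all arrays was used; 3323 genes had more than 1 probe past the filter, and other probes that differ by over 2 SE or in sign are given in the comparison that names the gene. Of 79 named genes 27 had another probe; over 24 such probes and comparisons of a called gene, 3 had the opposite sign and 15 differed by over 2 SE. The array design's probes of similar genes, such as metallothioneins and pregnancy-specific glycoproteins, may share signal.

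One linear model with a mean per group was fitted to all 8 arrays with limma (lmFit, eBayes), so that the groups share an estimate of the spread with 4 residual degrees of freedom and 5.13 prior ones. The contrasts were the 5 comparisons of groups, the interaction, that is the FA effect with rapamycin minus the FA effect without it, and the average effect of each drug. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of that contrast, and every adjusted p in the text is limma's. A gene whose probes were not detected on any array of a group has only a bound there: the brighter group's mean was set against the mean, over the dim group's arrays, of the higher of that array's lowest detected signal and the gene's own, and the ratio is written as at least that many fold.

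The 31 gene lists were fixed from general knowledge: glucocorticoid-induced genes, inflammatory genes, matrix metalloproteinases and plasminogen system, interferon-stimulated genes, cholesterol synthesis and uptake, fatty acid synthesis, ATF4 targets with amino acid and one-carbon metabolism, glycolysis and HIF targets, pentose phosphate pathway and NRF2 targets, ribosome biogenesis, cytosolic ribosomal proteins, translation initiation factors, autophagy and lysosome, S phase, G2 and M phase, cell cycle inhibitors and G1 cyclins, keratinocyte terminal differentiation, basal keratinocyte and hemidesmosome, activation-associated keratins, extracellular matrix and TGF-beta targets, metallothioneins, endoplasmic reticulum stress, heat shock proteins, mitochondrial respiratory chain, FOXO and insulin-feedback genes, mTOR and glucocorticoid receptor machinery, AP-1 and immediate early genes, and markers of fibroblasts, melanocytes, immune cells and endothelium. Of them 29 had at least 5 measured members and were tested with camera (preset correlation 0.01) in 5 contrasts, with Benjamini-Hochberg adjustment over the lists of a contrast. Lists share members: of 32 measured glucocorticoid-induced genes, 9 stand in another list. With the correlation between members estimated from the residuals, 0 of the 35 list calls held; fry, which asks whether a list's genes move one way and compares them with no other genes, called 2, 1, 5, 2 and 0 lists for FA against control, rapamycin against control, FA+rapamycin against FA, FA+rapamycin against rapamycin and the interaction, and with the block 1, 0, 1, 1 and 0. In 0 of the 35 called lists did the median, the mean and the test differ in sign, and in 0 did the median change sign with the scaling; with undetected genes at their bound the median of a called list moved by at most 0.0224, and that of the fibroblast markers, called only with the block, by 0.256. Attenuation was measured as the median interaction, signed by the direction of the average FA effect, over the genes called in that effect, whose estimate is independent of the interaction, and tested with fry, adjusted over the 6 selections of genes tried.

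Genes were named by rule: in FA against control, rapamycin against control and FA+rapamycin against FA the 8 largest rises and falls among called genes, in the other comparisons the 5 largest of each, or the 5 genes with the smallest p where none was called; for each called list up to 4 called members with the largest change in its direction, or else the 2 members with the smallest p; and in every comparison FKBP5, TSC22D3, PER1, DDIT4, DUSP1, KLF9, ZBTB16 and NR3C1. The groups, contrasts, filter, probe rule, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where the text says that a choice came later.

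Arrays of the same number were checked for pairing. The deviations from the group means correlated across genes between same-numbered arrays in all 6 pairs of groups, at 0.263 to 0.447. The 2 arrays of a group deviate in opposite directions by construction. That each of the 8 arrays correlated best with arrays of its own number therefore follows from these correlations and adds no support. By the criterion set for this, every pair above 0.1, the arrays were treated as paired by number. The basis is these data, since the labels name no shared batch or day. With 2 numbers over 4 groups there are 8 ways to align them. If the 2 arrays of each group differed along a common axis, the numbers could align on it by chance. The criterion therefore does not establish the pairing, and results with the block rest on a pairing taken from these same data. Values with the replicate number as a block are given where they change a call or move a count by over 1.5 times. The alternatives tried were no background correction, median scaling, cyclic loess, the deposited log2 values, no filter, a filter at detection p under 0.01 on all arrays, every probe on its own, only the groups compared, the replicate block, an intensity trend of the variance, an added threshold of 1.5-fold, each array left out in turn with and without the block, and for the lists the estimated correlation and fry, each with and without the block. An array left out without the block unbalances the replicate numbers, so the difference between them enters the comparison; results of both kinds of fit are given. Detection ran from 40.5% to 43.6% of probes per array.

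The fits were tested on simulated data. For simulated FA against control over 12398 genes, 200 of them changed, in 20 simulations, 68.4% of the genes changed by 1 on the log2 scale were recovered, 92.9% at 1.5, 97.1% at 2 and 99.4% at 3, and 4.81% of the calls were unchanged genes. A simulated rapamycin against control with no changed gene gave 0 calls on average. An attenuation of 0.4 was estimated at -0.393 and one of 0 at -0.00135. A list of 30 genes shifted by 0.3 was found for the simulated interaction in 100% of the simulations and an unshifted one in 0%. Each gene was simulated independently, with no difference between replicate numbers and no correlation between genes. The rates of false calls therefore do not carry over to these arrays, where same-numbered arrays deviate together.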

Results

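Total RNA of HaCaT cells, a spontaneously immortalized human keratinocyte line, was hybridised as biotinylated cRNA to Illumina bead arrays. The 8 arrays form 4 groups of 2: vehicle control (DMSO), 1 µM FA for 24 h, 1 µM rapamycin, and FA+rapamycin, in which 6 h of 1 µM rapamycin preceded 24 h of 1 µM FA. The labels do not spell out FA, which is read here as a glucocorticoid because the study's title concerns the function of the glucocorticoid receptor. The labels also leave open how long the cells of the rapamycin group were exposed. Rapamycin is an inhibitor of the mTOR kinase. Between 19143 and 20649 of 47316 probes were detected per array (40.5% to 43.6%), and the median signal was 92.5 to 94.3, against 88 to 89.5 for the negative control probes. Across probes, arrays of the same group correlated at 0.987 to 0.993 and arrays of different groups at 0.976 to 0.994. The number of arrays limits the precision of every comparison, and changes are given on the log2 scale ± SE of the fit.

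The comparison of FA with vehicle asks which transcripts respond to the glucocorticoid alone. FKBP5, a co-chaperone of the glucocorticoid receptor, rose by 3.26 ± 0.13 (9.6-fold, adjusted p = 5.6e-06). The matrix metalloproteinase MMP7 rose by 4.62 ± 0.24 (24.6-fold) and the acute-phase gene SAA1 by 2.79 ± 0.13. Further rises were those of the lipase-related gene PNLIPRP3 by 3.22 ± 0.29, the T-cell co-stimulatory ligand CD86 by 2.56 ± 0.21 and the transcription factor KLF9 by 2.43 ± 0.24. PHACTR3, a regulator of protein phosphatase and actin, and the transcription factor TFCP2L1 were not detected in control cells and were at least 7.65-fold and 8.14-fold higher with FA. In the other direction MMP10, a second matrix metalloproteinase, fell by 4.83 ± 0.60 on the log2 scale (28.4-fold lower, adjusted p = 0.00992), and the monocyte chemokine CCL2 fell by 2.18 ± 0.33. TNFRSF11B (osteoprotegerin) was not detected with FA and was at least 3.71-fold lower. CALB2 (calretinin) changed by -1.57 ± 0.26, the Wnt antagonist SOST by -1.50 ± 0.16, the matricellular gene CCN3 by -1.43 ± 0.18, the alcohol dehydrogenase ADH7 by -1.43 ± 0.20 and the membrane protein gene TMEM125 by -1.42 ± 0.17.

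Of 32 measured glucocorticoid-induced genes, 9 rose with FA over all genes tested, 17 rose adjusted over the list alone, and 15 rose with the replicate number as a block, called the block below. The list's median was 0.58 (camera adjusted p = 2.23e-19), with adjusted p = 0.347 with an estimated correlation. Besides FKBP5, TFCP2L1 and KLF9, the kinase gene SGK1 rose by 2.01 ± 0.19 and TSC22D3, which encodes the anti-inflammatory protein GILZ, by 1.68 ± 0.27 (adjusted p = 0.0314). DDIT4, an inhibitor of mTOR signalling, stood at 0.75 ± 0.28 (adjusted p = 0.477, or 0.0233 with the block). The MAP kinase phosphatase DUSP1 stood at 0.42 ± 0.12 (0.273), the transcription factor ZBTB16 at -0.13 ± 0.16 (0.895) and the receptor gene NR3C1 at -0.07 ± 0.15 (0.946). No PER1 probe passed the detection filter. Metallothioneins bind metal ions, and their list also names MTF1 and SLC30A1, which are not metallothioneins. Of its 8 measured genes, 3 rose over all genes and 6 adjusted over the list alone. The 3 were MT2A by 1.25 ± 0.18, MT1E by 1.14 ± 0.18 and MT1X by 0.91 ± 0.14. The median of this list was 0.75 (camera adjusted p = 1.8e-09, with adjusted p = 0.347 with an estimated correlation). MT2A and MT1X belong to both lists, and probes of such similar genes may share signal.

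Of 17 measured matrix metalloproteinases and members of the plasminogen system, MMP7 rose and MMP10 fell over all genes. The counts were 1 and 7 adjusted over the list alone, and 1 and 6 with the block. The list lay below the other genes, at a median of -0.41 (camera adjusted p = 0.00138, with adjusted p = 0.347 with an estimated correlation). The 21 measured inflammatory genes did not shift as a list (median -0.03, adjusted p = 0.953). Of them CCL2 fell while SAA1 and the prostaglandin synthase PTGS2 rose, PTGS2 by 1.92 ± 0.19 (a gene chosen after its value was seen). The counts were 2 higher and 3 lower adjusted over the list alone, and 3 and 5 with the block.

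Ribosome biogenesis genes lay higher with FA, all 35 with a positive change and a median of 0.22 (camera adjusted p = 2.72e-06, with adjusted p = 0.889 with an estimated correlation). With limma 0 of the 35 passed, 2 had an unadjusted p under 0.05 and 1 passed with the block. The transcription factor MYC stood at 0.92 ± 0.21 (adjusted p = 0.148, or 0.0136 with the block) and PES1 at 0.37 ± 0.15 (0.548). Genes of the G2 and M phases lay lower, 38 of 40 with a negative change and a median of -0.19 (camera adjusted p = 3.21e-05, with adjusted p = 0.889 with an estimated correlation). Here 0 of 40 passed with limma, with or without the block, and 0 had an unadjusted p under 0.05. The mitotic genes AURKB and BIRC5 stood at -0.29 ± 0.13 and -0.33 ± 0.18. Cholesterol synthesis and uptake genes had a median of -0.14 (camera adjusted p = 0.0389, with adjusted p = 0.889 with an estimated correlation). With limma 0 of 21 passed, 2 had an unadjusted p under 0.05, and 2 passed with the block. These were INSIG1, which retains the sterol-regulated factor SREBP in the endoplasmic reticulum, at -0.63 ± 0.17 (0.243, or 0.0396 with the block) and TM7SF2 at -0.60 ± 0.25 (0.553, or 0.04). The list calls ended for ribosome biogenesis without control replicate 2 (adjusted p = 0.869) and for G2 and M phase without control replicate 1 (0.0539) or FA replicate 2 (0.109). For cholesterol it ended without control replicate 1 (0.354), FA replicate 1 (0.0617) or FA replicate 2 (0.123). With the block kept in such fits, ribosome biogenesis lost its call without control replicate 2 (0.161), cholesterol without control replicate 1 (0.311) or FA replicate 2 (0.0671), and the other 4 lists kept theirs. The cholesterol call also ended with median scaling (0.077).

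In all, 76 of 12398 genes passed an adjusted p of 0.05 for FA against control in limma, 48 higher and 28 lower. At an unadjusted p under 0.05 there were 1042, where chance gives 620. With the block 245 passed, 125 higher and 120 lower. Second probes of a gene differed most for CALB2 (0.15 ± 0.18, of opposite sign), MT1E (0.07 ± 0.15), PHACTR3 (1.61 ± 0.18), SAA1 (1.40 ± 0.18) and TSC22D3 (2.62, 2.30 and 0.65). The other MMP7 probe changed by 5.17 ± 0.20. MMP7 was detected on 1 of 2 control arrays, SAA1 on 1 of 2 control arrays, and MMP10 and ADH7 on 1 of 2 FA arrays.

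The count of 76 for FA against control became 31 without FA replicate 1, 20 without FA replicate 2 and 46 without either FA+rapamycin array. Of 21 named genes past the test, 9 kept their call whichever array was left out. MMP10 and TMEM125 lost it without either FA array (adjusted p up to 0.0836 and 0.069), CCN3 and SOST without FA replicate 2 (0.0981 and 0.0504). The call was lost for ADH7 without either FA array or control replicate 2 (up to 0.204) and for TSC22D3 without any single control or FA array (up to 0.279). CCL2 and TNFRSF11B lost it without either FA array, either FA+rapamycin array or control replicate 2 (up to 0.2 and 0.204). MT2A lost it without any single FA or FA+rapamycin array (up to 0.187), and MT1E without those or control replicate 1 (up to 0.243). CALB2 lost it without any single FA, rapamycin or FA+rapamycin array (up to 0.279), and MT1X without any single control, FA or rapamycin array (up to 0.219). With the block kept in these fits 17 of the 21 held, and the call was lost for MT2A without FA replicate 1 (0.0913), MT1E without that array or control replicate 1 (up to 0.104), MT1X without those or control replicate 2 (up to 0.0913) and ADH7 without FA replicate 2 (0.0719). Without background correction MMP10, TNFRSF11B, CCL2, CALB2, ADH7 and TSC22D3 did not pass (adjusted p = 0.11, 0.186, 0.143, 0.11, 0.086 and 0.0604). With no detection filter MMP10 (0.0807), TNFRSF11B (0.122), CCL2 (0.125), CALB2 (0.149), CCN3 (0.0534), ADH7 (0.082), MT2A (0.082), MT1E (0.0969), MT1X (0.0575) and TSC22D3 (0.139) did not pass. With only these groups fitted CALB2 (0.126), ADH7 (0.0706), MT2A (0.104), MT1E (0.0825) and MT1X (0.0787) did not.

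**Figure D1:**
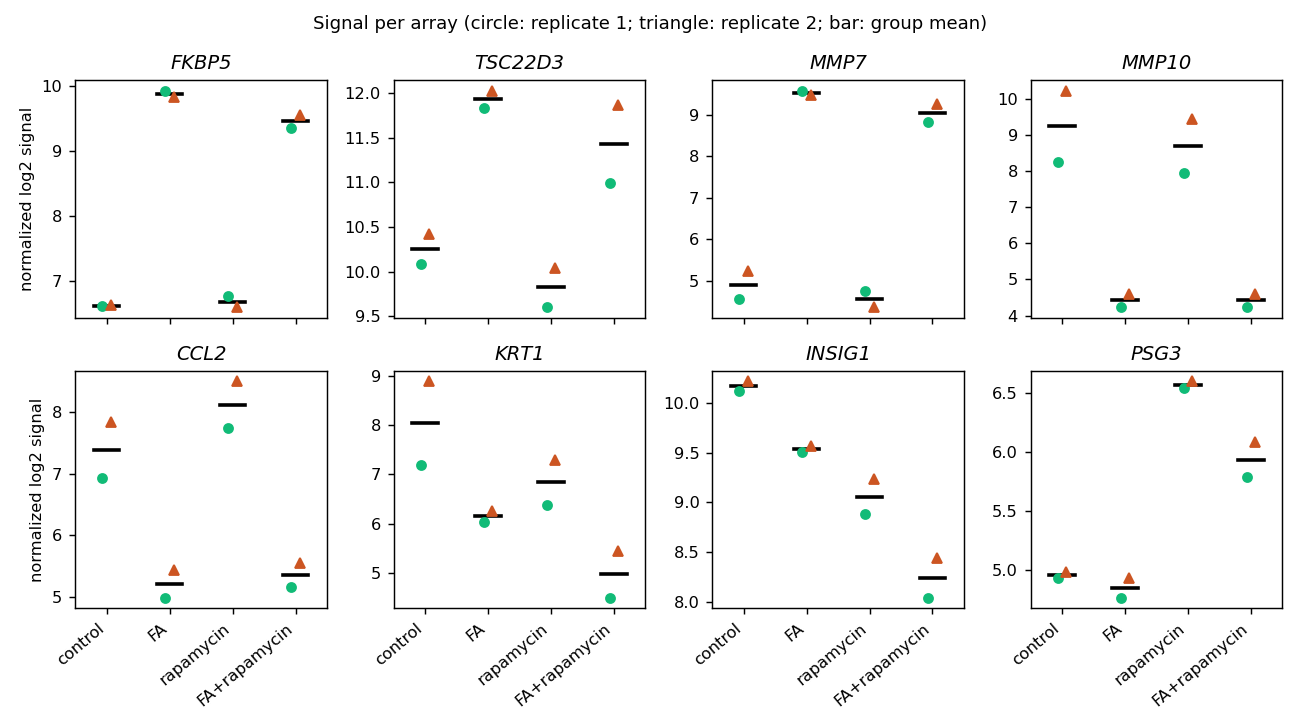
Normalized log2 signal of 8 genes on each of the 8 arrays, by group; circles are replicate 1, triangles replicate 2 and bars the group means. FKBP5 averaged 6.62 in control, 9.88 with FA, 6.68 with rapamycin and 9.46 with FA+rapamycin, and the 2 control arrays of MMP10 and KRT1 lay far apart (SD 1.4 and 1.2).

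Rapamycin against control asks what mTOR inhibition changes without the glucocorticoid. PSG3, of the pregnancy-specific glycoproteins, rose by 1.61 ± 0.14 (3.05-fold, adjusted p = 0.0118), and was the 1 gene past the test. PSG3 was dim in control, at a mean of 4.96, and without background correction it changed by 0.69, so the size of its rise is uncertain. Its family is of similar sequence, so probes may share signal. Genes of cholesterol synthesis and uptake lay lower, at a median of -0.43 (camera adjusted p = 9.94e-12, with adjusted p = 0.177 with an estimated correlation). Over all genes 0 of these 21 passed with limma, 14 had an unadjusted p under 0.05, 13 fell adjusted over the list alone and 2 fell with the block. INSIG1 stood at -1.11 ± 0.17 (adjusted p = 0.125, or 0.0107 with the block) and the sterol demethylase MSMO1 at -0.70 ± 0.12 (0.215, or 0.0418). Another MSMO1 probe gave 0.18 ± 0.15. Fatty acid synthesis genes had a median of -0.26 (camera adjusted p = 0.00112, with adjusted p = 0.393 with an estimated correlation), and 3 of 14 fell adjusted over the list alone, where 0 passed over all genes. The elongase ELOVL5 stood at -0.53 ± 0.12 and ACSS2, which makes acetyl-CoA, at -0.51 ± 0.13 (another ACSS2 probe at -0.04 ± 0.13).

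Metabolic lists lay lower in rapamycin-treated cells as well. The median was -0.13 for the mitochondrial respiratory chain (camera adjusted p = 2.42e-05, with adjusted p = 0.31 with an estimated correlation). SDHA, of complex II, stood at -0.47 ± 0.12 and NDUFB9, of complex I, at -0.43 ± 0.14. It was -0.10 for glycolysis and HIF targets (0.00112, with adjusted p = 0.31 with an estimated correlation). Aldolase C (ALDOC) stood at -1.15 ± 0.18 (0.125, or 0.00789 with the block) and PFKFB4 at -0.52 ± 0.13. Pentose phosphate and NRF2 targets had a median of -0.15 (0.00114, with adjusted p = 0.248 with an estimated correlation). The aldo-keto reductases AKR1B10 and AKR1C3 stood at -1.71 ± 0.40 and -1.18 ± 0.23 (0.47 and 0.233, or 0.000514 and 0.00883 with the block). ATF4 targets with amino acid and one-carbon genes had a median of -0.19 (2.27e-04, with adjusted p = 0.578 with an estimated correlation). NUPR1 stood at -0.68 ± 0.18 (another probe at -0.08 ± 0.19) and ATF5 at 0.35 ± 0.13. With limma 0 genes of these lists passed over all genes. Of 39, 31, 22 and 32 measured, 5, 6, 9 and 4 had an unadjusted p under 0.05, and adjusted over the list alone 2 glycolysis genes and 3 pentose phosphate and NRF2 genes fell.

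Keratinocyte terminal differentiation genes also lay lower with rapamycin, at a median of -0.18 (camera adjusted p = 7.98e-05, with adjusted p = 0.452 with an estimated correlation). The kallikreins KLK7 and KLK6 stood at -0.84 ± 0.17 (0.301, or 0.0496 with the block) and -0.68 ± 0.20 (0.531, or 0.0479), and another KLK6 probe at 0.07 ± 0.13. Genes of the G2 and M phases had a median of -0.20 (1.55e-05, with adjusted p = 0.613 with an estimated correlation), with NDC80 at -0.39 ± 0.15 and CDK1 at -0.34 ± 0.14. The glucocorticoid-induced list had a median of -0.13 (0.026, with adjusted p = 0.656 with an estimated correlation), with SGK1 at -1.06 ± 0.19 (0.215, or 0.0294 with the block) and the acyl-CoA synthetase ACSL1 at -0.73 ± 0.14 (0.233, or 0.0379). Lists that lay higher were ribosome biogenesis (median 0.15, 7.84e-04, with adjusted p = 0.641 with an estimated correlation; NOB1 0.51 ± 0.13, MYC 0.83 ± 0.21) and AP-1 and immediate early genes (0.16, 0.00508, with adjusted p = 0.452 with an estimated correlation; DUSP6 0.97 ± 0.17, adjusted p = 0.215, or 0.0481 with the block). Interferon-stimulated genes lay higher too (0.12, 0.0115, with adjusted p = 0.576 with an estimated correlation; IFIT2 0.74 ± 0.19, RIGI 0.56 ± 0.15). Over all genes 0 members of these 6 lists passed in limma. Of these lists, adjusted over the list alone, 1 differentiation gene fell, 1 glucocorticoid-induced gene rose and 3 fell, and 2 AP-1 genes rose. With the block the extracellular matrix and TGF-beta list was also called, higher with rapamycin (adjusted p = 0.0246, with adjusted p = 0.522 with an estimated correlation). Among the genes followed throughout, DDIT4 stood at -1.16 ± 0.28 (0.47, or 0.0107 with the block), KLF9 at -0.59 ± 0.24 (0.629) and TSC22D3 at -0.43 ± 0.27 (0.767). FKBP5 stood at 0.06 ± 0.13 (0.951), DUSP1 at 0.14 ± 0.12 (0.847), ZBTB16 at -0.00 ± 0.16 (0.998) and NR3C1 at -0.14 ± 0.15 (0.89; another probe at 0.05 ± 0.15).

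Rapamycin against control gave 1 gene past the threshold, 919 genes with an unadjusted p under 0.05 where chance gives 620, and 45 genes with the block (15 higher, 30 lower). PSG3 lost its call without any one of the control or rapamycin arrays (adjusted p 0.0798 to 0.214), leaving 0 genes, as it did without background correction (0.0545), with no filter (0.0586) or with only these groups fitted (0.126). PSG3 held its call with the block kept, whichever array was left out. Of the 12 list calls 5 held whichever array was left out. Without control replicate 1 the calls ended for ATF4 targets (adjusted p = 0.504, the median turning to 0.03) and interferon-stimulated genes (0.258), and without control replicate 2 for glucocorticoid-induced genes (0.853, median 0.02), ribosome biogenesis (0.311, median -0.08) and terminal differentiation (0.438, median 0.06). Without rapamycin replicate 1 they ended for AP-1 genes (0.0603), glucocorticoid-induced genes (0.462, median 0.00), interferon-stimulated genes (0.364) and ribosome biogenesis (0.106), and without rapamycin replicate 2 for G2 and M phase (0.169). These fits take in the difference between the replicate numbers. Of the 12 calls 5 held with the block kept as well. Those of ATF4 targets (0.791, median 0.01), interferon-stimulated genes (0.399) and glycolysis genes (0.0516) ended without control replicate 1, and those of ribosome biogenesis (0.865, median -0.01), glucocorticoid-induced genes (0.378) and terminal differentiation (0.258) without control replicate 2. Without rapamycin replicate 1 the interferon (0.141) and AP-1 (0.0729) calls ended. Without background correction the glucocorticoid-induced call ended (0.0564).

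FA+rapamycin against FA asks what rapamycin changes in cells that also receive the glucocorticoid. Cholesterol synthesis and uptake genes lay lower, at a median of -0.33 (camera adjusted p = 2.29e-09, with adjusted p = 0.177 with an estimated correlation). INSIG1 stood at -1.30 ± 0.17 (adjusted p = 0.0549, or 0.00588 with the block; another probe at -0.45 ± 0.17) and DHCR7, the last enzyme of one branch of the pathway, at -0.71 ± 0.13 (0.173, or 0.0341). Fatty acid synthesis genes lay lower as well, at -0.31 (2.41e-05, with adjusted p = 0.228 with an estimated correlation), with ELOVL5 at -0.70 ± 0.12 (0.137, or 0.0254) and fatty acid synthase (FASN) at -0.73 ± 0.15 (0.218). Respiratory chain genes had a median of -0.18, 37 of 39 negative (9.07e-09, with adjusted p = 0.177 with an estimated correlation), with NDUFB9 at -0.72 ± 0.14 (0.2, or 0.0467) and SDHA at -0.51 ± 0.12. Over all genes 0 members of these 3 lists passed in limma. Adjusted over the list alone 9 of 21 cholesterol genes, 3 of 14 fatty acid genes and 2 of 39 respiratory chain genes fell, and with the block 3, 2 and 1 did.

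The genes with the smallest p in FA+rapamycin against FA, all at an adjusted p of 0.0549, were the growth factor carrier FGFBP1 (-1.21 ± 0.14), ACSL1 (-1.09 ± 0.14), the small GTPase RAB7B (-1.57 ± 0.20), PSG3 (1.08 ± 0.14) and the retinoic acid carrier CRABP2 (-1.11 ± 0.14). Each passed with the block (0.00588, 0.00634, 0.00684, 0.00684 and 0.01). Further lists lay lower. These were terminal differentiation (median -0.21, 3.03e-05, with adjusted p = 0.425 with an estimated correlation; KLK7 -0.66 ± 0.17, CSTA -0.58 ± 0.17) and pentose phosphate and NRF2 targets (-0.20, 0.00211, with adjusted p = 0.177 with an estimated correlation; AKR1B10 -1.65 ± 0.40, AKR1C3 -1.01 ± 0.23, or 0.00202 and 0.0114 with the block). So did ATF4 targets (-0.11, 0.017, with adjusted p = 0.696 with an estimated correlation; ATF5 0.40 ± 0.13, SLC1A4 -0.41 ± 0.14) and glucocorticoid-induced genes (-0.17, 0.017, with adjusted p = 0.696 with an estimated correlation; ACSL1, and ERRFI1 at 0.92 ± 0.15). When adjusted over the list alone 2 NRF2 genes fell, and 2 glucocorticoid-induced genes rose and 2 fell. Lists that lay higher were ribosome biogenesis (0.21, 2.67e-04, with adjusted p = 0.662 with an estimated correlation; NOB1 0.48 ± 0.13, UBTF -0.45 ± 0.14, with other UBTF probes of opposite sign at 0.21 ± 0.20 and 0.29 ± 0.15) and extracellular matrix and TGF-beta targets (0.15, 0.0122, with adjusted p = 0.398 with an estimated correlation; COL12A1 0.81 ± 0.14 and CCN2 1.25 ± 0.24, or 0.0325 and 0.00953 with the block). Other probes of COL12A1 and CCN2 gave 0.09 ± 0.14 and 0.31 ± 0.16. The others were AP-1 genes (0.06, 0.017, with adjusted p = 0.425 with an estimated correlation; DUSP6 0.73 ± 0.17, SPRED1 0.71 ± 0.21, the latter 0.0368 with the block) and cytosolic ribosomal proteins (0.04, 0.017, with adjusted p = 0.398 with an estimated correlation; RPL28 0.79 ± 0.18, 0.0163 with the block, and RPL13 0.33 ± 0.12). Over all genes 0 members of these 8 lists passed in limma. Of the matrix and AP-1 genes 3 and 1 rose adjusted over the list alone, and 5 and 1 with the block. With the block matrix metalloproteinases and the 5 measured fibroblast markers were also called, both lower (0.0319 each, with adjusted p = 0.519 with an estimated correlation for both). The fibroblast markers had a median of -0.33, or -0.08 with undetected genes at their bound. KLF9 stood at -0.89 ± 0.24 (0.357, or 0.0254 with the block), DDIT4 at -0.70 ± 0.28 (0.52, or 0.0484), TSC22D3 at -0.50 ± 0.27 (0.614) and FKBP5 at -0.43 ± 0.13 (0.421). NR3C1 stood at -0.15 ± 0.15 (0.796), DUSP1 at 0.06 ± 0.12 (0.899) and ZBTB16 at -0.01 ± 0.16 (0.992).

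FA+rapamycin against FA gave 0 genes past the threshold in limma, against 1128 with an unadjusted p under 0.05 (620 by chance) and 114 with the block (40 higher, 74 lower). Without either control array, 14 genes passed. Of the 11 list calls 6 held whichever array was left out. Without FA replicate 1 the calls ended for AP-1 genes (adjusted p = 0.317), ATF4 targets (0.145) and matrix genes (0.0682), and without FA replicate 2 for ribosomal proteins (0.156) and glucocorticoid-induced genes (0.173). Without FA+rapamycin replicate 1 they ended for AP-1 genes (0.117), ribosomal proteins (0.0901), matrix genes (0.07) and glucocorticoid-induced genes (0.284), and without FA+rapamycin replicate 2 for ATF4 targets (0.248). When the block was kept 6 of the 11 held as well. The calls ended for glucocorticoid-induced genes (0.153), matrix genes (0.0503) and AP-1 genes (0.323, median -0.00) without FA replicate 1, for ATF4 targets and ribosomal proteins without FA replicate 2 (0.389 and 0.135) or FA+rapamycin replicate 1 (0.108 and 0.0626), and for AP-1 genes without FA+rapamycin replicate 1 (0.134).

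FA+rapamycin against rapamycin asks what FA changes in cells pre-treated with rapamycin. The exposure time of the rapamycin group is not given, and a difference in duration between these groups would enter the comparison. MMP7 rose by 4.47 ± 0.24 (22.1-fold, adjusted p = 4.69e-05), PNLIPRP3 by 3.25 ± 0.29 and SAA1 by 2.96 ± 0.13. PHACTR3 and TFCP2L1, not detected with rapamycin alone, were at least 8.0-fold and 6.43-fold higher. MMP10 fell by 4.27 ± 0.60 on the log2 scale (19.3-fold lower, adjusted p = 0.015). CCL2 changed by -2.76 ± 0.33, CALB2 by -2.07 ± 0.26 and TMEM125 by -1.45 ± 0.17, and TNFRSF11B, not detected with FA+rapamycin, was at least 5.19-fold lower. Of the 32 glucocorticoid-induced genes 10 rose, 17 adjusted over the list alone and 15 with the block, at a median of 0.53 (camera adjusted p = 4.13e-18, with adjusted p = 0.344 with an estimated correlation). FKBP5 rose by 2.77 ± 0.13, SGK1 by 2.68 ± 0.19, KLF9 by 2.13 ± 0.24 and TSC22D3 by 1.60 ± 0.27. DDIT4 stood at 1.21 ± 0.28 (0.128, or 0.00146 with the block), DUSP1 at 0.34 ± 0.12 (0.337), ZBTB16 at -0.14 ± 0.16 (0.83) and NR3C1 at -0.08 ± 0.15 (0.919).

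In the same comparison 2 of 8 measured genes of the metallothionein list rose, 7 adjusted over the list alone and 6 with the block. The 2 were MT2A by 1.08 ± 0.18 and MT1X by 1.02 ± 0.14, at a list median of 0.76 (camera adjusted p = 4.79e-10, with adjusted p = 0.344 with an estimated correlation). Of the matrix metalloproteinases and plasminogen system MMP7 rose, and MMP10 and the protease ADAMTS1 (-0.92 ± 0.15) fell. The counts were 1 and 6 adjusted over the list alone, and 1 and 5 with the block. The list's median was -0.36 (3.4e-04, with adjusted p = 0.344 with an estimated correlation). Ribosome biogenesis genes lay higher, at 0.27 (1.99e-06, with adjusted p = 0.814 with an estimated correlation), with RRP1B at 0.62 ± 0.18 and POLR1C at 0.49 ± 0.17. Interferon-stimulated genes lay lower, at -0.19 (0.00246, with adjusted p = 0.814 with an estimated correlation), with IFI27, not detected with FA+rapamycin, at least 1.28-fold lower (adjusted p = 0.141) and ISG20 at -0.45 ± 0.16 (0.359). With limma 0 of 35 and 0 of 32 genes of these lists passed, with or without the block, and 8 and 4 had an unadjusted p under 0.05. Of the 21 inflammatory genes 2 rose and 1 fell, 3 and 3 adjusted over the list alone. With the block the translation initiation list (higher, adjusted p = 0.0423) and the S phase list (lower, 0.0274) were called too, with adjusted p = 0.841 and 0.971 with an estimated correlation.

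FA+rapamycin against rapamycin gave 91 genes past the threshold, 52 higher and 39 lower, with 1275 at an unadjusted p under 0.05 (620 by chance) and 318 with the block (147 higher, 171 lower). The count became 57 without either FA array, 29 and 27 without rapamycin replicate 1 or 2, and 35 and 23 without FA+rapamycin replicate 1 or 2. Of 17 named genes past the test 7 kept their call whichever array was left out. Among the others, TNFRSF11B lost it without either FA+rapamycin array (adjusted p up to 0.13), MMP10, CCL2 and TMEM125 without those or rapamycin replicate 2 (up to 0.15, 0.0848 and 0.0676), CALB2 without those or rapamycin replicate 1 (up to 0.116), and KLF9 without rapamycin replicate 1 (0.0597). MT1X lost it without either rapamycin array or FA+rapamycin replicate 2 (up to 0.138), TSC22D3 without those or either FA array (up to 0.259), and MT2A and ADAMTS1 without any single FA, rapamycin or FA+rapamycin array (up to 0.28 and 0.257). The interferon list lost its call without rapamycin replicate 1 (0.279) or FA+rapamycin replicate 2 (0.276). With the block kept in these fits 14 of the 17 genes held, and MT2A without any single rapamycin or FA+rapamycin array (up to 0.15), MT1X without rapamycin or FA+rapamycin replicate 2 (up to 0.0626) and ADAMTS1 without rapamycin replicate 1 (0.0616) did not. The interferon list lost its call without the same 2 arrays (0.159 and 0.163). Without background correction MMP10, TNFRSF11B, CALB2, ADAMTS1 and TSC22D3 did not pass (0.147, 0.0822, 0.0759, 0.102 and 0.0619). With no filter MMP10 (0.0921), CCL2 (0.0557), TNFRSF11B (0.0706), CALB2 (0.0584), ADAMTS1 (0.0738), MT2A (0.106) and TSC22D3 (0.129) did not pass. CALB2 had a second probe of opposite sign (0.20 ± 0.18). Other probes gave 1.68 ± 0.18 for PHACTR3, 1.48 ± 0.18 for SAA1 and 2.58, 2.55 and 0.62 for TSC22D3.

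FA+rapamycin against control gives the effect of both drugs together. MMP7 rose by 4.14 ± 0.24 (17.6-fold, adjusted p = 9.33e-05), SAA1 by 3.05 ± 0.13, PNLIPRP3 by 2.88 ± 0.29, FKBP5 by 2.83 ± 0.13 and KLF9 by 1.54 ± 0.24. PHACTR3 and TFCP2L1 were at least 7.78-fold and 6.26-fold higher. MMP10 changed by -4.82 ± 0.60, the suprabasal keratin KRT1 by -3.06 ± 0.52 (8.36-fold lower, adjusted p = 0.0172), the membrane raft protein gene MAL by -2.75 ± 0.36, CALB2 by -2.69 ± 0.26 (its second probe by 0.17 ± 0.18) and SOST by -2.16 ± 0.16. TSC22D3 stood at 1.17 ± 0.27 (0.0557, or 0.00228 with the block), DUSP1 at 0.48 ± 0.12 (0.0666, or 0.0253), DDIT4 at 0.05 ± 0.28 (0.946), ZBTB16 at -0.14 ± 0.16 (0.694) and NR3C1 at -0.22 ± 0.15 (0.487). Other probes gave 1.65 ± 0.18 for PHACTR3, 1.47 ± 0.18 for SAA1 and 1.84, 1.78 and 0.15 for TSC22D3.

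The lists were not tested as sets for FA+rapamycin against control, and their members are counted. Of the 32 glucocorticoid-induced genes 10 rose and 1 fell (16 and 1 adjusted over the list alone, 17 and 1 with the block). In the metallothionein list 5 of 8 measured genes rose (7 adjusted over the list alone). Of 21 cholesterol synthesis and uptake genes 6 fell, and adjusted over the list alone 1 rose and 11 fell (10 fell with the block). Of 39 terminal differentiation genes 2 rose and 3, KRT1 among them, fell (4 and 8 adjusted over the list alone, 4 and 8 with the block). Of 35 ribosome biogenesis genes 2 rose (9 adjusted over the list alone, 11 with the block). In all 365 genes passed, 160 higher and 205 lower, with 2299 at an unadjusted p under 0.05 (620 by chance) and 1171 with the block (537 higher, 634 lower). Of the calls 43.8% were higher, against 52.4% of 275 with median scaling and 50.7% of 469 without background correction, so the direction of the majority changed with the processing. The count became 215 without either FA array, 237 without either rapamycin array, 87 and 84 without FA+rapamycin replicate 1 or 2, and 206 without control replicate 2. Of 12 named genes past the test 8 kept their call whichever array was left out. KRT1 and MAL lost it without either FA+rapamycin array (adjusted p up to 0.163 and 0.0622), MMP10 without FA+rapamycin replicate 1 (0.0534) and KLF9 without FA+rapamycin replicate 2 (0.0755), and KRT1 also without background correction (0.056) or with no filter (0.0664). All 12 held in these fits when the block was kept.

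The interaction asks whether rapamycin alters the response to FA, which is the question in the study's title. Because the exposure time of the rapamycin group is not given, a difference in duration from FA+rapamycin would enter the interaction. It would also enter the attenuation and the average effects below. FKBP5 had an interaction of -0.49 ± 0.18, KLF9 of -0.30 ± 0.34, TSC22D3 of -0.07 ± 0.38, DUSP1 of -0.08 ± 0.17, DDIT4 of 0.46 ± 0.40, NR3C1 of -0.01 ± 0.21 and ZBTB16 of -0.01 ± 0.22, each at an adjusted p of 1. Other TSC22D3 probes gave -0.04, 0.25 and -0.02. The smallest p belonged to the pyruvate dehydrogenase phosphatase PDP1 (-1.17 ± 0.20), PTPRZ1 (0.76 ± 0.17), IFI27 (-0.76 ± 0.17), SNORD15B (0.76 ± 0.18) and GCFC2 (-0.74 ± 0.17), also at an adjusted p of 1. IFI27 was not detected with FA+rapamycin, so its value rests on a signal below detection in that group and is not exact. In limma 0 of 12398 genes passed, with or without the block. Without the block 276 had an unadjusted p under 0.05, where chance gives 620. That fit leaves the difference between replicate numbers in its spread, so a count below chance is not evidence against an interaction. The SE of an interaction had a median of 0.21 over the genes. Even PDP1, at -1.17 ± 0.20, did not pass, so differences well above that SE in a single gene could also go uncalled.

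Over the 315 genes called in the average FA effect, the median interaction, signed so that a negative value means a smaller FA response with rapamycin, was 0.03 (fry adjusted p = 0.536 over 6 selections). The response was smaller with rapamycin for 137 of the 315 genes, and its median size was 0.65 without and 0.70 with rapamycin. The median was 0.01 for the 152 genes raised by FA (adjusted p = 0.828) and 0.05 for the 163 genes lowered by it (adjusted p = 0.617). It was -0.08 (adjusted p = 0.536) over the 76 genes called in FA against control and 0.11 (adjusted p = 0.436) over the 91 called in FA+rapamycin against rapamycin. These last selections each favour one direction, and the 836 genes called with the block gave 0.05 (adjusted p = 0.536). Without control replicate 1, control replicate 2 or FA replicate 1 the median over the average FA effect changed sign, with the block kept or not, and across the arrays left out without the block it ranged from -0.06 to 0.12. Genes of the G2 and M phases made the 1 list called for the interaction, 34 of 40 with a positive value and a median of 0.16 (camera adjusted p = 0.00332, with adjusted p = 0.992 with an estimated correlation). With limma 0 of the 40 passed and 0 had an unadjusted p under 0.05; CENPE stood at 0.33 ± 0.24 and UBE2C at 0.31 ± 0.24. The call ended without control replicate 1 (0.153), FA+rapamycin replicate 1 (0.965, median -0.03), FA replicate 2 (0.539) or rapamycin replicate 2 (0.795). With the block kept it ended without FA+rapamycin replicate 1 (0.237, median 0.07) or control replicate 2 (0.11, median 0.10).

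The FA effect without rapamycin and the FA effect with it, which share no array, correlated across the 12398 genes at Pearson's r = 0.691 and Spearman's rho = 0.474, and genes are not independent replicates. Both comparisons called 60 genes, 41 higher and 19 lower, where independent lists would share 0.558. Both tests use the same variance estimate of each gene, so their calls are not independent and chance overlap can exceed that number. Of the genes called without rapamycin 76 of 76, and of those called with it 90 of 91, had the same sign in the other comparison. The rapamycin effects without and with FA, which share no array either, correlated at 0.558 and 0.466.

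**Figure D2:**
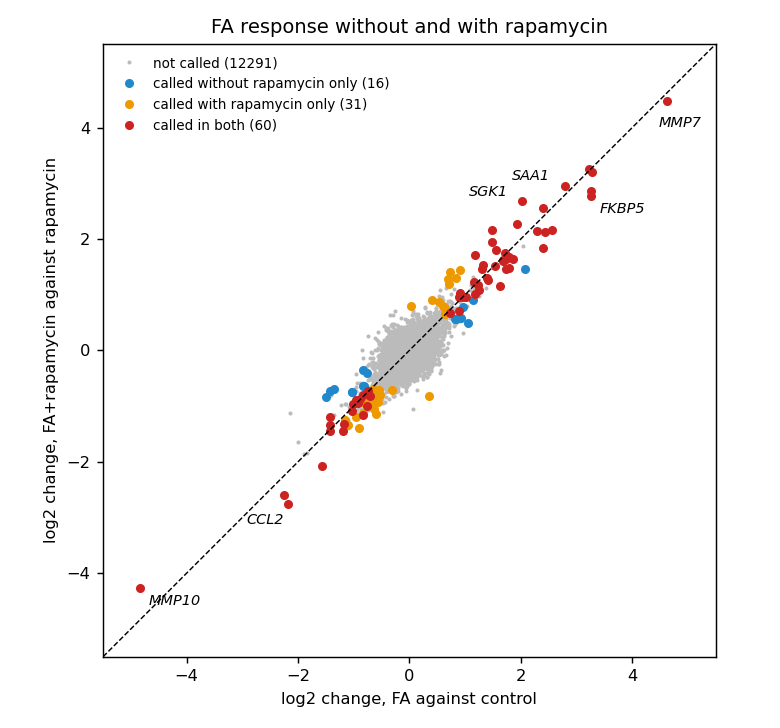
Log2 change with FA in cells without rapamycin (horizontal) against that in cells with rapamycin (vertical), a point per gene for 12398 genes; colours mark genes past an adjusted p of 0.05 in both comparisons (60), without rapamycin only (16) or with rapamycin only (31), and the dashed line marks equal change. MMP7 lies at 4.62 and 4.47, and MMP10 at -4.83 and -4.27.

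Averaged over both rapamycin states, the 4 arrays with FA differed from the 4 without in 315 genes, 152 higher and 163 lower, with 1891 at an unadjusted p under 0.05 (620 by chance) and 836 with the block (376 higher, 460 lower). Of these calls 48.3% were higher, against 52.1% of 238 with median scaling and 52.5% of 318 without background correction. The count of 315 became 154 and 144 without FA replicate 1 or 2, 148 and 138 without rapamycin replicate 1 or 2, and 164 and 145 without FA+rapamycin replicate 1 or 2. Averaged over both FA states, rapamycin changed 61 genes, 19 higher and 42 lower, with 1780 at an unadjusted p under 0.05 and 550 with the block (225 higher, 325 lower). Of these calls 31.1% were higher, against 41.5% with median scaling. The count of 61 became 145 and 32 without control replicate 1 or 2, 10 and 15 without FA replicate 1 or 2, 14 and 20 without rapamycin replicate 1 or 2, and 10 and 18 without FA+rapamycin replicate 1 or 2.

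Of the 29 lists tested, 13 were called in no comparison without the block, with medians between -0.49 and 0.13. Among them fibroblast markers, translation initiation factors and S phase were called with the block, as given above. The lowest was that of the fibroblast markers in FA+rapamycin against rapamycin, at -0.24 with undetected genes at their bound. The smallest adjusted p of each without the block was 0.0596 for heat shock proteins, 0.0648 for translation initiation factors, 0.0648 for S phase, 0.0704 for fibroblast markers, 0.125 for mTOR and glucocorticoid receptor machinery, 0.212 for immune cell markers and 0.272 for basal keratinocyte genes. It was 0.407 for inflammatory genes, 0.407 for activation-associated keratins, 0.56 for cell cycle inhibitors and G1 cyclins, 0.585 for FOXO and insulin-feedback genes, 0.635 for autophagy and lysosome genes and 0.784 for endoplasmic reticulum stress genes. Markers of melanocytes (3 measured, median -0.05 in FA against control) and endothelium (1 measured, -0.61) were too few to test.

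**Figure D3:**
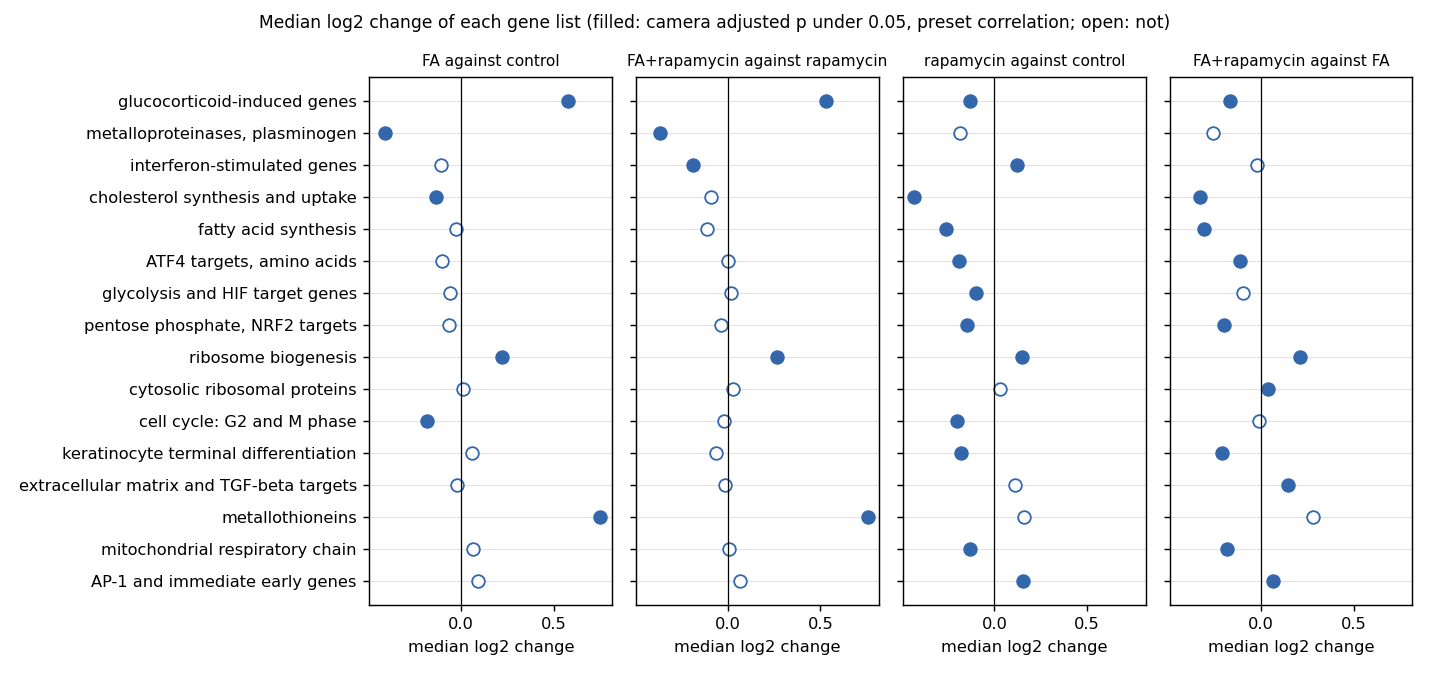
Median log2 change of the members of 16 gene lists in the 4 comparisons of a drug with its reference; filled points have a camera adjusted p under 0.05 with the preset correlation, which 0 list calls kept with an estimated correlation. The glucocorticoid-induced list lies at 0.58 and 0.53 for FA without and with rapamycin, and the cholesterol list at -0.43 and -0.33 for rapamycin without and with FA.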

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

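Both tests of the G2 and M phase list were chosen after its result was seen.

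Genes of the G2 and M phases drew attention because their response to FA differed between cells with and without rapamycin, by a test of the difference itself. Camera with the preset correlation gave an adjusted p of 0.00332 for the interaction, with a median of 0.16, while in limma 0 of 40 members passed, with or without the block, and 0 had an unadjusted p under 0.05. With the correlation between the list's members estimated from the arrays, the adjusted p of camera was 0.992. That setting called 0 lists in any comparison, and gave 0.347 even for the glucocorticoid-induced list in FA against control. It therefore cannot decide whether variation between arrays that these genes share explains the result, which stays open. The list's mean on replicates 1 and 2 was 9.21 and 9.10 in control and 9.06 and 8.90 with FA. With rapamycin it was 9.09 and 8.87, and with FA+rapamycin 9.12 and 8.79. In the last 2 groups the gap was wider than the median interaction of 0.16, so shared variation of that size was present. Part of it may follow the replicate number, since replicate 2 was lower in each group. Within each replicate number the interaction was positive, at a median of 0.18 over the members in number 1 and 0.11 in number 2. Of 40 members 32 were positive in number 1, 30 in number 2 and 24 in both. Members with unrelated signs would overlap as much, so the 24 show no agreement member by member. Fits that leave out 1 array without the block also take in the difference between the numbers; the highest adjusted p among them was 0.965. With the block kept, the call ended without FA+rapamycin replicate 1 (0.237) or control replicate 2 (0.11), while the median stayed positive in all 8 such fits (0.07 to 0.23). Since either of 2 arrays ends the call and the direction holds without each, an effect of 1 array and an effect of the drugs cannot be told apart here.

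Probes without a single gene symbol were left out of the comparisons of genes, and they carry signal. Of 6079 such probes above background, 17 passed an adjusted p of 0.05 in FA against control (13 higher, 4 lower), 17 in FA+rapamycin against rapamycin (12 higher, 5 lower) and 75 in FA+rapamycin against control (33 higher, 42 lower). In limma 0 passed in rapamycin against control, FA+rapamycin against FA and the interaction, with 351, 427 and 201 at an unadjusted p under 0.05, where chance gives 304. What these probes measure is not given in the sources used here, and no explanation was tested.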

How the results depend on the processing

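The replicate block with an estimated correlation, with fry and with an array left out were chosen after the data were seen, and the other alternatives were planned. Among called named genes, 497 of the results under other settings kept direction and side of the threshold and 38 were weaker; among called lists, 151 kept it and 129 were weaker. With an array left out, 319 results of genes kept it and 89 were weaker, and 248 of lists kept it, 28 were weaker and 4 turned in camera's direction. With an array left out and the block kept, 394 results of genes kept it and 14 were weaker, and 257 of lists kept it and 23 were weaker. Among named genes not called, 45 passed under another setting (36 of them with the block), 15 with an array left out and 142 with the block as well. Cyclic loess, the deposited log2 values and every probe tested moved no count of genes by over 1.5 times. Unless stated, the cause of a change was not tested.

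Genes past the threshold in FA against control numbered 33 with no filter, 38 with only the groups compared and 245 with the replicate block. Those in rapamycin against control numbered 0 with no background correction, no filter, the strict filter or only the groups compared, 5 with an intensity trend and 45 with the block. FA+rapamycin against FA gave 10 with the trend and 114 with the block, FA+rapamycin against rapamycin 50 with no filter and 318 with the block, and FA+rapamycin against control 128 with only the groups compared, where fewer arrays leave fewer degrees of freedom, and 1171 with the block. The average FA effect gave 198 with a threshold of 1.5-fold, which is stricter by construction, and 836 with the block; the average rapamycin effect gave 93 with no background correction, 34 with no filter, 96 with the trend and 550 with the block. The block, which removes variation shared by arrays of a number, ended no call of a named gene.

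The estimated correlation called 0, 0, 0, 0 and 0 lists in FA against control, rapamycin against control, FA+rapamycin against FA, FA+rapamycin against rapamycin and the interaction, and the block with an estimated correlation 0, 0, 0, 0 and 0. In the same order fry called 2, 1, 5, 2 and 0, fry with the block 1, 0, 1, 1 and 0, and no background correction called 2 in the interaction. The attenuation was -0.0771 over genes called in FA against control. ZBTB16, near the detection limit, turned sign with no background correction in rapamycin against control (0.0018), FA+rapamycin against FA (0.0091) and the interaction (0.0072), and with median scaling in rapamycin against control (0.0057).

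With each array left out in turn, the lone array of its group was assumed to vary like the other groups. Without the block these fits also take in the difference between replicate numbers, which the block removes. Counts ran without the block, and then with it, from 20 to 66 and 74 to 206 in FA against control, 0 to 1 and 3 to 53 in rapamycin against control, 0 to 14 and 0 to 116 in FA+rapamycin against FA, and 23 to 123 and 73 to 351 in FA+rapamycin against rapamycin. They ran from 84 to 449 and 333 to 1030 in FA+rapamycin against control, 138 to 377 and 420 to 720 in the average FA effect, 10 to 145 and 107 to 409 in the average rapamycin effect, and stayed at 0 in the interaction. Lists called ran from 4 to 11 and 6 to 9 in FA against control, 10 to 16 and 12 to 15 in rapamycin against control, 9 to 14 and 10 to 14 in FA+rapamycin against FA, 5 to 8 and 5 to 7 in FA+rapamycin against rapamycin, and 0 to 7 and 0 to 6 in the interaction.

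The attenuation ran from -0.0593 to 0.1236 without the block and -0.0526 to 0.0906 with it. Over both kinds of fit, changes that turned sign ran, in FA against control, from -0.3759 to 0.118 (ZBTB16) and -0.234 to 0.0963 (NR3C1), and in rapamycin against control from -0.0358 to 0.1602 (FKBP5), -0.1657 to 0.1624 (ZBTB16) and -0.293 to 0.0126 (NR3C1). They ran in FA+rapamycin against FA from -0.2569 to 0.2371 (ZBTB16) and -0.3167 to 0.0136 (NR3C1), for NR3C1 in FA+rapamycin against rapamycin from -0.233 to 0.0726, and in FA+rapamycin against control from -0.2774 to 0.3846 (DDIT4) and -0.3029 to 0.0252 (ZBTB16). In the interaction they ran from -0.5078 to 0.3584 (TSC22D3), -0.6375 to 0.0417 (KLF9), -0.2552 to 0.2388 (ZBTB16) and -0.1765 to 0.1538 (NR3C1). Adjusted p of lists that so turned ran in rapamycin against control from 7.23e-05 to 0.853 (glucocorticoid-induced), 7.2e-14 to 0.791 (ATF4) and 2.65e-12 to 0.865 (ribosome biogenesis), and in the interaction from 2.15e-10 to 0.965 (G2 and M phase). With the block 0 turned in camera's direction. A block by slide was not run, since the files name no slide. The median signal of 92.5 to 94.3 lay near the negative controls' 88 to 89.5, which limits folds of dim genes, as for MMP10 with FA.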

Other observations

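The test of the other MMP7 probe was chosen after its result was seen, and the genes named here for the average effects and the replicate numbers were chosen after their values were seen.

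Averaged over both FA states, rapamycin raised ANKRD1, a muscle ankyrin-repeat gene, by 1.59 ± 0.18, PSG5 by 1.51 ± 0.16, PSG3 by 1.35 ± 0.10, the Wnt antagonist DKK1 by 1.06 ± 0.10, the matricellular gene CCN2 by 1.01 ± 0.17 and BMP4 by 1.01 ± 0.12. It lowered AKR1B10 (-1.68 ± 0.29), the growth factor gene NRG4 (-1.26 ± 0.18), INSIG1 (-1.21 ± 0.12), RAB7B (-1.20 ± 0.14), ALDOC (-1.10 ± 0.13) and AKR1C3 (-1.09 ± 0.16). Among genes of sterol and fatty acid synthesis IDI1 fell by 0.69 on the log2 scale, DHCR7 by 0.67, FASN by 0.66, LSS by 0.64, MSMO1 by 0.62 and ELOVL5 by 0.62. Other probes differed by over 2 SE for CCN2 (0.20 ± 0.11), INSIG1 (-0.71 ± 0.12), LSS (-0.17 ± 0.10) and MSMO1 (0.13 ± 0.11, of opposite sign). Some raised genes were dim without rapamycin. BMP4 averaged 4.54 in control and 4.56 with FA, CCN2 4.68 and 4.95, and PSG5 4.85 and 5.02. In the same groups PSG3 averaged 4.96 and 4.85, and ANKRD1 5.4 and 4.72. The median of the deposited log2 values was 4.43 on each array, so the sizes of these rises are uncertain. The genes named for the average rapamycin effect were not followed one by one with arrays left out.

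Both average effects called 14 genes, where independent lists would share 1.55; with the block they called 168, against 37.1. In this balanced design the errors of the 2 effects are uncorrelated, but both tests use the same variance estimate of each gene. Their calls are therefore not independent, and chance overlap can exceed 1.55 and 37.1. FA and rapamycin both lowered 10 genes: INSIG1 (-0.73 ± 0.12 with FA, -1.21 ± 0.12 with rapamycin), SOST (-1.17 ± 0.11 and -0.99 ± 0.11), the retinoic acid carrier CRABP2 (-0.99 and -0.95), the adhesion gene CNTN1 (-0.93 and -0.91), the water channel AQP3 (-0.76 and -0.98), FGFBP1, PTGS1, CYP4F11, PDLIM7 and NHERF1. Both raised RGCC (1.23 ± 0.20 and 1.15 ± 0.20). FA raised and rapamycin lowered KLK7 (0.79 ± 0.12 and -0.75 ± 0.12), PRR15L (0.58 and -0.96) and ARTN (0.57 and -0.60), and 0 genes in limma went the other way (14 with the block). Other probes differed by over 2 SE for CNTN1 (-0.23 and -0.50) and PDLIM7 (-0.13 and -0.06, and 0.01 and -0.08), and for INSIG1 with rapamycin (-0.71). INSIG1 averaged 10.17 in control, 9.54 with FA, 9.06 with rapamycin and 8.24 with both. Across all genes the effects correlated at Pearson's r = 0.163, and genes are not independent replicates.

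MMP7 rose and MMP10 fell with FA, although both are matrix metalloproteinases. The other MMP7 probe changed by 5.17, which argues against a signal of 1 probe for MMP7. MMP10 had 0 other probes above background, so for MMP10 a signal of 1 probe and a change of the transcript cannot be told apart. Over the fits that leave out 1 array, the smallest change of either gene was 3.84 in size, which argues against an effect of 1 array on the direction, although the MMP10 call ended without FA replicate 1 (adjusted p = 0.0836) or FA replicate 2 (0.0799). With the replicate number as a block, the MMP10 call held without each of the 8 arrays.

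Arrays of the same number deviated from their group means together, with correlations across genes from 0.263 to 0.447 over the 6 pairs of groups. With other normalizations the lowest was 0.26, which argues against the scaling of the arrays as the whole cause. Among the 9004 genes detected on all arrays the lowest was 0.354, so the correlations do not rest on dim probes alone. Noise independent between arrays could not produce such correlations, so this value is no test of it. Cultures, days or hybridisations shared by a number stay open, since the labels name none. A chance alignment of the numbers over the groups stays open too, and no biological explanation was tested.

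Replicate 2 differed from replicate 1 in 511 genes, 330 higher and 181 lower, among them the follistatin gene FST (-1.45), the circadian factor TEF (-1.07), the apoptosis ligand TNFSF10 (1.24) and the chemokine CXCL8 (1.02). G2 and M phase, S phase, ribosome biogenesis and ATF4 lists lay lower in replicate 2 (medians -0.20, -0.21, -0.21 and -0.21). Inflammatory, FOXO, basal keratinocyte and glucocorticoid-induced lists lay higher (0.22, 0.20, 0.18 and 0.17). With the preset correlation 12 lists were called, and with an estimated correlation 0 (smallest adjusted p = 0.414).

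Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes as the split by FA, namely that split itself. Comparing 4 arrays with 4, it called 266 genes and the highest other, the split by rapamycin, 25. Over all 35 splits this is a share of 0.0286, under 0.05. That share takes the 8 arrays as separate units, though the 2 arrays of a group may be technical duplicates. The pairing adopted above would call for the 18 splits with 2 arrays of each number on both sides. These are too few for a share under 0.05 (1 of 18 is 0.0556), with the same real value and highest other. The splits therefore do not exclude chance for the average FA effect. For rapamycin 2 of the 35 splits gave as many genes, the real one with 25 and the split by FA with 266. Since the FA split follows the other treatment, this count does not settle whether chance can be excluded for rapamycin. The 33 splits that follow neither drug called at most 2 genes in limma, 32 of the 35 splits called none, and the split by replicate number called 0. Fits of these splits leave the drug effects in the spread, which lowers the calls of splits that cross the drugs. With group means fitted, 511 genes differed between the numbers, so the low counts are not a clean reference.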
